A study of Bdellovibrio bacteriovorus HD100 with 6 samples.

How the data were processed

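RNA from 6 samples of attack-phase Bdellovibrio bacteriovorus HD100 was compared, 3 held in HEPES buffer and 3 in nutrient broth (NB). Per the labels' protocols, rRNA was depleted, libraries were made with a TruSeq standard mRNA kit and 50 bp single-end reads were sequenced. Reads were aligned with Bowtie2, per the submitters' processing notes. The version, the read counter, its use of strand and the genome build are not given in the sources used here. Coordinates are printed as the deposited tables give them, on a single chromosome.

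The authors deposited whole-number read counts per gene, not normalized, for 3628 features: 3586 protein-coding genes, 36 tRNA genes and 6 rRNA genes. The tRNA and rRNA features were listed at 0 in every sample. The authors also deposited RPKM values for the 3586 protein-coding genes. For genes with at least 200 counts, these RPKM values differed by a median of 0.08% and at most 1.19% from the count divided by the sample total and by the gene length minus 49 bases. The same deposited table gives a ratio of NB over HEPES, which matched the quotient of mean RPKM values to 1e-06 in 3431 of 3431 genes with a ratio above 0. Its deposited p-values matched a paired test on RPKM, with samples matched by replicate number, to 1e-06 in 3463 of 3463 genes. Product names were taken from the deposited annotation. It called 1288 genes hypothetical, and the products of 20 genes are not reported here.

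Samples were grouped by their labels, and all 6 were used. Changed genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM factors, edgeR's default filter on low counts by group, glmQLFit and the two-sided quasi-likelihood F-test, with no block. The Benjamini-Hochberg adjusted p had to lie under 0.05. A second count took genes that also changed at least 2-fold. Standard errors (SE) of log2 fold changes were obtained as the absolute log2 fold change divided by the square root of F. Abundances in CPM (depth-scaled counts, not scaled by gene length) use TMM factors unless called shares of reads, which use library totals alone. The most abundant genes are those with the most reads.

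30 gene lists were fixed by product name or locus tag. They were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 30 lists. Camera compares a list with the other genes, whereas fry, an alternative, tests whether a list's genes move. The lists, the tests, most alternatives and the rule for named genes were set before the data were examined. The rule took genes with adjusted p under 0.05, at least 2-fold change, a mean of at least 10 CPM and no overlap between the values of both media. From these, the 12 largest rises and 12 largest falls among genes with a product name and the 2 largest of each among hypothetical genes were named. It added, per list, up to 3 called members in the direction most took and 1 in the other, every predation-cycle and flagellin filament locus, and the 3 most abundant genes of each medium. Any other gene named was chosen after its values were seen.

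Alternatives were RLE and upper-quartile factors, library totals alone, 2 other filters on low counts, DESeq2 1.42.0, a replicate block, a test against a 2-fold change, limma on log2(RPKM + 1) and log2(RPKM + 0.1), camera with an estimated correlation, fry, and leaving out each sample in turn. Curated lists (also with an estimated correlation), HEPES counts thinned to the NB depth and upper-quartile factors for named genes were added after seeing the data. Single values per sample were compared with two-sided exact permutation tests in scipy 1.17.1, whose smallest possible p with 3 against 3 samples is 0.1.

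The count test was tested on simulated data over 2935 genes passing the filter. These used the mean of each gene over both media and the real library sizes and dispersions. Most simulated genes were unchanged, and as many were raised as lowered. The simulation therefore does not test calls where most genes change, as here, or the choice of scale. It recovered 41 of 50 genes raised 2-fold, 44 of 48 lowered 2-fold, 50 of 50 raised 4-fold and 47 of 48 lowered 4-fold, with 7 calls among 2739 unchanged genes. The list test called a simulated raised list and 0 of 29 unchanged ones. Simulated genes varied independently, whereas the estimated correlation among ribosomal protein genes was 0.66. The simulation therefore does not test false calls on lists of correlated genes. Total counts ran from 1512935 to 6358704 per sample, so that 3 counts, the floor of detection, corresponded to between 0.47 and 1.98 CPM of the library total. Intervals and floors cover counting error only.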

Results

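RNA was sequenced from attack-phase Bdellovibrio bacteriovorus HD100, the free-swimming stage of a predatory bacterium that grows inside the periplasm of Gram-negative prey. Cells from 24 h predatory cultures on Escherichia coli were passed through a 0.45 µm filter. They were then held for 4 h at 30 °C in HEPES buffer, which offers no nutrients, or in nutrient broth (NB), a medium of peptides and extract. Both media held 4 mM CaCl2 and 2 mM MgCl2, and each had 3 samples. The HEPES samples held 6358704, 2748972 and 5303625 counts, and the NB samples 2037663, 1830603 and 1512935. The labels number the samples as replicates but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All counted features were B. bacteriovorus loci. RNA of the prey was not analysed here, and rRNA and tRNA genes were listed at 0 in all 6 samples.

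The comparison of both media asks how extracellular nutrients alter expression in attack-phase cells, a response that the series title sets beside late growth inside prey. In NB, most tested genes on the lists for ribosomal proteins, translation, respiration, ATP synthase and the citric acid cycle rose, although camera called none of these lists with an estimated correlation (adjusted p = 0.398 for each). Most genes for the flagellum fell with TMM scaling, although 18 of them held a higher share of reads. Of 47 ribosomal protein genes tested, 46 rose and 1 fell, with a median log2 fold change of 3.85. Of 52 flagellar genes, 46 fell and 0 rose by edgeR (46 and 0 also at an unadjusted p under 0.05 and by DESeq2), with a median of -2.59, whereas 29 were lower and 18 higher as shares of reads. Over the genome, 2566 of 3041 genes tested by edgeR changed, 1360 higher and 1206 lower in NB, and 2034 changed at least 2-fold (1101 higher and 933 lower). A further 545 protein-coding genes had too few counts to be tested.

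The libraries differed in how far a few genes dominated them. The 100 most abundant genes held 72.5% ± 0.458 of counts in HEPES and 48.8% ± 1.00 in NB (SD, n = 3; exact permutation p = 0.1, the smallest possible). TMM factors ran from 0.458 to 0.487 in HEPES and from 2.052 to 2.166 in NB. Log2 fold changes on library totals therefore lay 2.16 above those on the TMM scale, almost the same for every gene (SD 0.0182). As shares of reads, 2421 genes were higher and 400 lower, so that 85.8% of changed genes were higher in NB against 53% with TMM. All 1360 genes that rose with TMM were also higher as shares of reads. Of the 1206 that fell, 400 were lower as shares too, 586 were higher and 220 did not pass the test. Fold changes below are on the TMM scale, and the share of reads is given wherever it turns a direction.

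**Figure D1:**
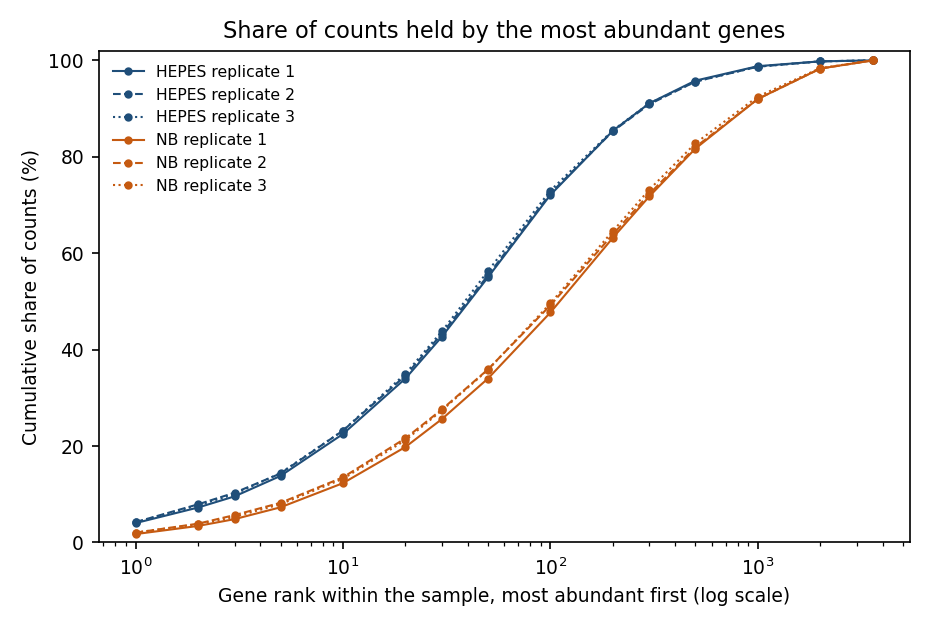
Cumulative share of counts (percent, vertical axis) held by the most abundant genes of each sample, by rank on a log axis; each line is 1 of the 3 HEPES or 3 NB samples. At rank 100 the HEPES samples lie between 72.1% and 73.0% and the NB samples between 47.7% and 49.6%.

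Genes of the translation machinery rose together. Ribosomal protein L36 (Bd2953.1, bases 2862895 to 2863008) went from 1.85 ± 0.31 to 214 ± 7.44 CPM (SD, n = 3), a log2 fold change of 6.77 ± 0.19 (SE). Ribosomal proteins L14 (Bd2965) and L3 (Bd2976) rose by 4.95 ± 0.14 and 4.87 ± 0.14. Together the 47 genes took 0.0409% ± 0.00818 of reads in HEPES and 2.55% ± 0.197 in NB. The only ribosomal entry that fell was Bd1517 (-3.87), annotated as similar to a 40S protein, which is a eukaryotic subunit, from 118 HEPES and 13 NB counts in total. Of 17 translation factors, 15 rose, among them ribosome recycling factor (Bd3784, 4.58), elongation factor G (Bd2979, 4.21) and elongation factor Ts (Bd3782, 3.97). The SUI1-type factor Bd0232 fell (-2.52), and initiation factor IF-1 (Bd0321, -1.31) fell with TMM but was higher as a share of reads (0.85). Without 5 translation factor entries whose annotation names another or a less specific function, 11 of 13 rose and 2 fell. Of 22 aminoacyl-tRNA synthetases, which charge tRNAs, 18 rose, led by both phenylalanyl subunits (Bd1638, 4.41; Bd1637, 3.34) and the glycyl enzyme (Bd1147, 3.40). An alanyl-tRNA synthetase gene, Bd0501, fell by 3.37. The threonyl (Bd1617, -0.52) and arginyl (Bd2027, -0.41) genes fell with TMM and were higher as shares of reads (1.64 and 1.75). Counts adjusted over the list alone were equal for these 3 lists. Camera placed all 3 above the other genes, with adjusted p = 9.89e-24, 2.08e-04 and 0.0025, but adjusted p = 0.398 for each with an estimated correlation.

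Energy metabolism moved the same way. In the respiratory chain list 35 of 44 genes rose (36 adjusted over the list alone), 5 fell and 4 did not pass. NADH-quinone oxidoreductase chain 3 (Bd3892) rose by 6.05 ± 0.36, cytochrome c3 (Bd1607) by 4.96 ± 0.22 and oxidoreductase chain 6 (Bd3890) by 4.35 ± 0.29. Bd3892 and Bd3890 had only 7 and 11 HEPES counts in total, so the size of their rises is uncertain. The 5 that fell were a thioredoxin (Bd2208, -3.06), a thiol oxidoreductase rather than a chain subunit, CtaA (Bd2217, -2.24), cytochrome c biogenesis genes Bd3255 (-1.34) and Bd2826 (-0.76), and hydrogenase cytochrome b Bd1410 (-0.60). As shares of reads, Bd3255 (0.82), Bd2826 (1.40) and Bd1410 (1.56) were higher, and Bd2217 did not pass the test. In the ATP synthase list, 9 of 10 genes rose, including Bd3903 (5.61), Bd3902 (4.85) and Bd3896 (4.69). The exception, Bd3401 (-1.75), encodes the flagellum-specific ATPase of the export apparatus and was slightly higher as a share of reads (0.41). Of 26 genes on the citric acid cycle list, 22 rose, with citrate synthase (Bd2511) at 4.51 ± 0.25, isocitrate dehydrogenase (Bd3723) at 4.37 ± 0.23 and an aconitase (Bd2784) at 4.03 ± 0.23. A second aconitase gene, Bd3178 (-0.92), a fumarase, Bd2151 (-0.31), and a cyclic nucleotide-binding regulator, Bd2879 (-0.84), fell with TMM but were higher as shares of reads (1.24, 1.86 and 1.32). Without 12 members whose annotation names another or a less specific function, 12 of 14 rose and 2 fell, and all 14 were higher as shares of reads. Removing 11 such members from the respiratory chain list left 29 of 33 higher and 2 lower, with 33 higher as shares. Counts adjusted over the list alone were equal for ATP synthase and the citric acid cycle. Camera adjusted p was 1.63e-05, 6.06e-04 and 1.99e-04 for the 3 lists, and 0.398 for each with an estimated correlation.

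Most genes of fatty acid synthesis and of purine and pyrimidine synthesis rose. On the fatty acid synthesis list 13 of 15 genes rose and 0 fell by edgeR (0 also at an unadjusted p under 0.05, by DESeq2 and by limma), with Bd2012 (short-chain dehydrogenase/reductase, 4.82), Bd2010 (beta-ketoacyl synthase, 4.22) and Bd2011 (acyl carrier domain, 3.90) in front. In purine and pyrimidine synthesis 15 of 18 rose, among them the carbamoyltransferase Bd0855 (3.55), adenylosuccinate synthetase (Bd1460, 3.08) and a dihydroorotase (Bd1072, 2.90). Orotidine 5-phosphate decarboxylase (Bd2996) fell with TMM (-0.69) and was higher as a share of reads (1.48). Counts adjusted over the list alone were equal. Without 7 mismatched members of the fatty acid list, 7 of 8 tested genes rose and 0 fell. Camera adjusted p was 0.00188 and 0.0122 (0.0143 and 0.0158 without mismatched members), and 0.398 for both with an estimated correlation.

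**Figure D2:**
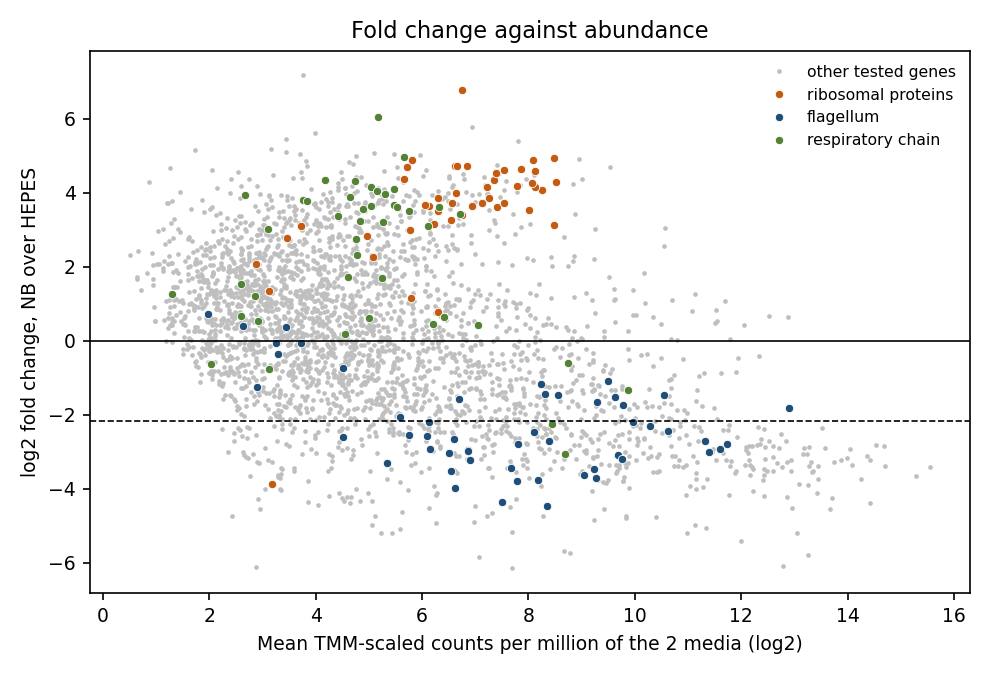
Log2 fold change (NB over HEPES, TMM scale) of each tested gene against its mean TMM-scaled CPM (log2), with ribosomal protein, flagellar and respiratory chain genes coloured. The dashed line lies 2.16 below 0, where a gene's share of reads did not differ; 46 of 47 ribosomal protein genes rose, and flagellar genes scatter around the dashed line.

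Most flagellar and flagellin genes fell on the TMM scale, but only in part as shares of reads. Among flagellar genes the largest falls were those of FlgG, a rod protein of the basal body (Bd0531, -4.47 ± 0.12), the transcriptional activator FlbD (Bd3408, -4.37 ± 0.14) and the export protein FliO (Bd3326, -3.97 ± 0.15), all lower as shares of reads too. Together the 52 flagellar genes took 2.80% ± 0.0224 of reads in HEPES and 2.49% ± 0.0897 in NB. Of the 6 flagellin filament loci, 5 fell with TMM, and 4 were higher as shares of reads. The falls were in Bd0408 (-3.09), Bd3052 (-2.93), Bd0604 (-1.83), Bd0606 (-1.47) and Bd0410 (-1.18). As shares of reads Bd0408 and Bd3052 were lower, and Bd0604 (0.33), Bd0606 (0.70) and Bd0410 (0.99) were higher. Bd3342 did not pass with TMM (0.39, adjusted p = 0.182 by edgeR), passed as a rise with upper-quartile factors (0.64, adjusted p = 0.0313) and was higher as a share (2.56). Flagellins are paralogs, and how reads that match several of them were counted is not known, so their separate values are uncertain. Both lists gave equal counts adjusted over the list alone. Camera adjusted p was 1.16e-13 for the flagellum and 0.0313 for the flagellins, with adjusted p = 0.398 for both with an estimated correlation. On library totals the flagellin call was lost (camera adjusted p = 0.125). All 6 flagellin loci are also on the flagellum list, so the calls of these lists are not separate results.

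The type IV pilus list divided into 15 genes that fell and 8 that rose (equal adjusted over the list alone), but 14 were higher and 7 lower as shares of reads. The largest falls were in genes of Flp (tight adherence) pili, a separate machine: Bd0111 (secretion ATPase, -3.96 ± 0.09), Bd0110 (TadB, -3.81 ± 0.10) and Bd0112 (annotated as PilQ, -3.73 ± 0.08), all lower as shares of reads too. Bd0112 went from 20800 ± 755 to 1570 ± 50.5 CPM. A pseudopilin, Bd1591, rose by 2.87. Camera adjusted p was 0.0122, but 0.398 with an estimated correlation, 0.0559 on library totals and 0.92 in a list without Flp and other mismatched genes, where 8 rose and 7 fell with TMM (median 0.85), and 14 were higher and 1 lower as shares of reads.

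Of 14 loci tied in earlier work to the predatory cycle, 12 were tested, and 8 fell, 2 rose and 2 did not pass (equal adjusted over the list alone), while 8 were higher and 3 lower as shares of reads. The host-interaction locus gene Bd0108 (bases 96873 to 97178), where mutations are found in prey-independent strains, fell by 3.73 ± 0.09. The D-Ala-D-Ala carboxypeptidase Bd3459, of a family that acts on prey cell wall, fell by 4.40 ± 0.21. The sigma-70 family factor Bd3318 fell by 2.45 ± 0.10. All 3 were lower as shares of reads too, while the GGDEF protein Bd1434 (-2.30) did not pass on that scale. The pilin gene pilA (Bd1290, -1.40), Bd1075 (-1.34), and the GGDEF genes Bd0367 (-0.78) and Bd0742 (-0.41) fell with TMM and were higher as shares of reads (0.77, 0.82, 1.39 and 1.76). The deacetylase genes Bd0468 (-0.32) and Bd3279 (-0.34) did not pass with TMM (adjusted p = 0.0558 and 0.181 by edgeR) and were higher as shares (1.84 and 1.82). The histidine kinase gene Bd3125 (0.82) and Bd0314 (0.91) rose, the latter from 21 HEPES and 67 NB counts in total. Bd0816 (40 and 14 counts) and Bd3460 (60 and 13 counts) were too low to test. Camera adjusted p for the list was 0.0545, and between 0.0349 and 0.424 over the alternatives (0.398 with an estimated correlation). Of the fits that left out a sample, it passed without HEPES replicate 2 (0.0434) and without NB replicate 1 (0.044), 2 (0.0411) or 3 (0.0403). The lowest value, 0.0349, came from another of the alternatives. The calls of Bd0314 (adjusted p = 0.058) and Bd0742 (0.0536) were lost by edgeR without HEPES replicate 1, that of Bd0742 without NB replicate 1 (0.0716) and with upper-quartile factors (0.249), and that of Bd0314 by DESeq2 (0.141). Bd3279 passed without NB replicate 3 (-0.57, adjusted p = 0.0135), and Bd0468 passed as a fall with RLE factors (-0.43, adjusted p = 0.0146).

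**Figure D3:**
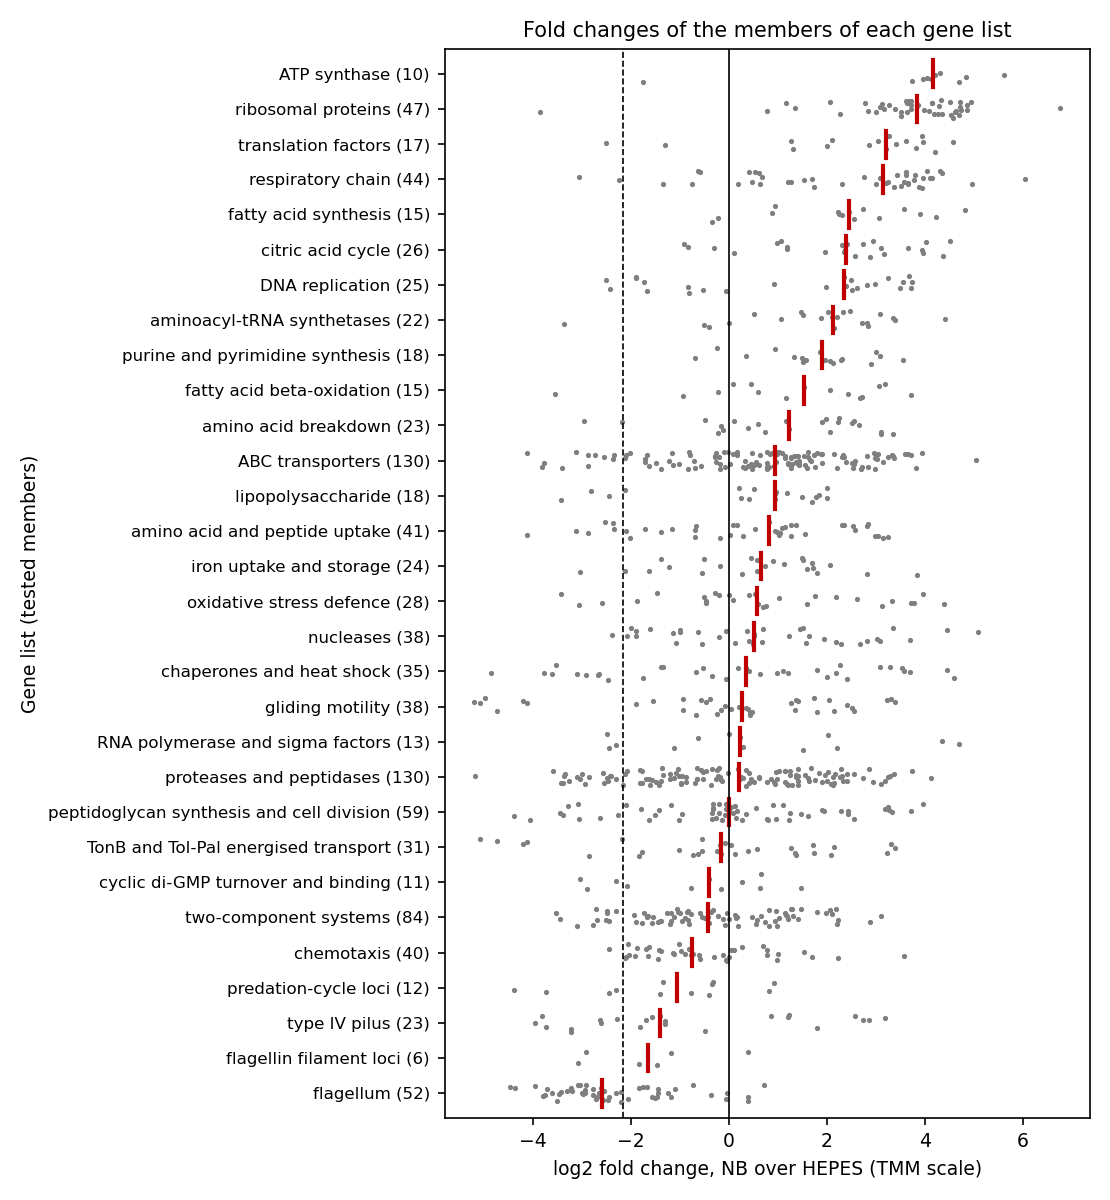
Log2 fold change (NB over HEPES, TMM scale, horizontal axis) of each tested member of the 30 gene lists; points are genes, red bars are list medians, and the dashed line lies 2.16 below 0, where shares of reads were equal. Medians run from -2.59 for the flagellum, with the dashed line between it and 0, to 4.17 for ATP synthase.

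Besides those above, the largest rises among genes with a product name and a mean of at least 10 CPM were as follows. A cyclophilin-type prolyl isomerase (Bd0177) rose by 5.78 ± 0.21, ribonuclease HII (Bd2116) by 5.09 ± 0.51 and an esterase (Bd0899) by 5.08 ± 0.24. An alcohol dehydrogenase (Bd0898) rose by 5.01 ± 0.21 and the translocase subunit YajC (Bd2235) by 4.98 ± 0.26. Bd1610, annotated as an Fe3+ transport permease, rose by 5.05 ± 0.35. It lies in the run Bd1604 to Bd1612 with cytochrome c and molybdopterin oxidoreductase genes, so a role in iron transport is uncertain. Bd3848, annotated as involved in the peptidyltransferase reaction of translation, rose by 4.94 ± 0.18. It lies beside ribosomal protein gene Bd3849 but was not on the ribosomal protein list. Several named rises rested on few HEPES reads, such as 4 counts in total for Bd2116 and 4 for Bd3903. Others were 6 for Bd3902, 7 each for Bd3892 and Bd2764, and 13 for Bd2953.1. Of hypothetical genes, Bd0008 had 1 HEPES and 308 NB counts, a ratio of read shares of 825 (exact 95% interval 147 to 32700). Bd0318 had 3 and 242, a ratio of 216 (73 to 1050).

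Among genes with a product name, the largest fall was in an RCC1-repeat gene (Bd2486), which went from 8020 ± 442 to 189 ± 5.8 CPM (-5.41 ± 0.09). The 12 largest also held a predicted periplasmic or secreted lipoprotein (Bd3620, -5.20 ± 0.11) and a gene cluster annotated as adventurous gliding and TolQ-type transport, with Bd0416 (-5.21), Bd0417 (-5.09), Bd0415 (-4.99) and Bd0420 (-4.74). A trypsin-family protease (Bd0994, -5.19), a phage integrase (Bd2025, -4.99), the small heat shock protein Hsp20 (Bd3630, -4.86), a sigma-54 interaction protein (Bd1891, -4.79), an RTX-domain gene (Bd2346, -4.77) and a transcriptional regulator (Bd0801, -4.73) completed the 12. Among hypothetical genes with a mean of at least 10 CPM, Bd2302 (-6.15) and Bd0523 (-6.09) fell furthest. All 14 of these were lower as shares of reads too. Every named rise and fall of these 2 groups had adjusted p of at most 1.41e-07 by edgeR. The same direction in all 3 NB against all 3 HEPES samples was required by the rule that named them.

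Genes of protein turnover, stress and uptake divided. Among 130 proteases and peptidases 61 rose and 55 fell (105 higher and 17 lower as shares of reads), from the zinc protease Bd1552 (4.13), SohB-type Bd2188 (3.73) and the membrane protease Bd2667 (3.38) to Bd0994. Of 38 nucleases 18 rose and 12 fell (33 and 0 as shares of reads), with RNase P protein (Bd3913, 4.45) and an exonuclease (Bd2232, 3.69) up, and an SNase homologue (Bd1431, -2.39) down with TMM but not past the test as a share. In the chaperone list 17 of 35 rose, among them FKBP-type Bd3764 (4.45), ClpB (Bd3700, 3.57) and the 60 kDa inner membrane protein Bd3912 (4.60), and 14 fell (26 higher and 9 lower as shares of reads). Oxidative stress genes rose in 15 of 28 cases and fell in 7 (25 and 3 as shares of reads), with thioredoxin-like Bd2764 (4.39), glutaredoxin Bd1310 (3.96) and Mn/Fe superoxide dismutase Bd3617 (3.78) up, and Cu/Zn superoxide dismutase Bd0295 (-3.43) down. Of 130 ABC transporter genes 81 rose and 30 fell (116 and 9 as shares of reads), with solute-binding proteins Bd2191 (3.94) and Bd3421 (3.72) up and the amino acid-type binding protein Bd2651 (-4.12) down. Amino acid and peptide uptake had 21 of 41 higher and 13 lower (33 and 4 as shares of reads), with Bd0358 (3.24), Bd2189 (3.14) and Bd0360 (3.05) up. Iron uptake and storage had 12 of 24 higher and 6 lower (22 and 1 as shares of reads). Genes that rose included Bd2707 (3.84), a translation-associated GTPase, Bd0338 (2.81), a nucleotide-binding protein, and siderophore transport gene Bd2385 (1.80), while Bd1113 (FrpA-like, -3.04) fell. Of 31 TonB and Tol-Pal genes 11 rose and 12 fell (24 and 5 as shares of reads), with Bd0419 (TolR-type, -4.20) down. Camera adjusted p for these 8 lists was 0.873, 0.323, 0.873, 0.541, 0.22, 0.659, 0.659 and 0.659. The named members that fell here were lower as shares of reads too, except Bd1431. Camera, which compares with the other genes, gave a downward direction for proteases (median 0.19, mean 0.03) and for chaperones (median 0.34, mean 0.17), where the median of all tested genes was 0.22. Without mismatched members, 11 of 26 chaperone genes rose and 11 fell, and 13 of 24 oxidative stress genes rose and 5 fell. Likewise, 19 of 38 uptake genes for amino acids and peptides rose and 12 fell, and 10 of 21 iron genes rose and 5 fell.

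Amino acid breakdown had 16 of 23 genes higher and 3 lower (21 and 1 as shares of reads), with glycine cleavage H protein (Bd0266, 3.34), urocanase (Bd2751, 3.11) and glutamate dehydrogenase (Bd0717, 3.10) up and homogentisate dioxygenase (Bd3185, -2.96) down. Its camera adjusted p of 0.0667 became 0.0139 on library totals, 0.0425 with no filter on low counts and 0.0452 without NB replicate 3, in a range up to 0.424 over the alternatives. Beta-oxidation had 11 of 15 higher and 2 lower (14 and 1 as shares of reads; camera adjusted p = 0.127), with Bd1973 (3.71), Bd2095 (3.06) and Bd1850 (2.71) up and the thiolase Bd2070 (-3.56) down. In DNA replication 15 of 25 rose and 9 fell, while 21 were higher and 1 lower as shares of reads (0.145). Gyrase subunit B (Bd0004, 3.73), polymerase III gamma and tau (Bd3731, 3.71) and single-strand binding protein (Bd1582, 3.68) rose, and Bd2142 (-2.51), a histidine kinase by annotation, fell with TMM but did not pass as a share. Without such mismatched members the list passed with the preset correlation (adjusted p = 0.0167) but not with an estimated correlation (adjusted p = 0.437). RNA polymerase and sigma factors divided evenly, 5 higher and 5 lower of 13, but 10 and 2 as shares of reads (0.659), with the core genes annotated as alpha (Bd2983, 4.69), beta (Bd2984, 4.36) and omega (Bd1569, 2.20) up and ECF sigma factor Bd0881 (-2.50) down on both scales.

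Among 59 genes of peptidoglycan synthesis and cell division 22 rose and 20 fell (22 and 19 adjusted over the list alone, 49 and 8 as shares of reads). Named rises were MraY (Bd3201, 3.33) and 2 mismatched members, Bd2769 (3.97), an outer membrane protein, and solute-binding Bd3421 (3.72). Without 14 mismatched members 17 of 49 rose and 18 fell, with 41 higher and 7 lower as shares of reads. Camera placed the full list above the other genes (adjusted p = 0.873), although its median was -0.01, or 2.15 as a share of reads. Lipopolysaccharide genes rose in 12 of 18 cases and fell in 4, and 14 were higher and 2 lower as shares of reads (0.873). Bd0807 (2.01), Bd1500 (1.70) and Bd2367 (1.49) were up and glycosyltransferase Bd0618 (-3.43) was down. Without 5 mismatched members 9 of 14 lipopolysaccharide genes rose and 3 fell. Of 38 gliding genes 19 rose and 14 fell, but 31 were higher and 6 lower as shares of reads (0.89). Their median was 0.28 and their mean -0.09, and camera placed them below the other genes. Genes Bd2375 (3.40), Bd2376 (3.31) and Bd2377 (3.22) rose while the Bd0415 to Bd0420 cluster fell. Of 40 chemotaxis genes 10 rose and 23 fell (0.207), but 34 were higher and 1 lower as shares of reads. Histidine kinase Bd2406 (-2.45) fell on both scales, receptors Bd3256 (-2.13) and Bd1872 (-2.11) did not pass as shares, and receptor Bd1340 (2.23) rose. Two-component genes had 27 higher and 42 lower of 84, but 71 and 8 as shares of reads (0.351), with Bd3101 (-3.53), Bd1258 (-3.45) and Bd3779 (-3.11) lower on both scales and Bd2893 (3.11) higher. Cyclic di-GMP genes had 3 of 11 higher and 6 lower, but 7 and 2 as shares of reads (0.212), with Bd2421 (-3.04) and Bd2325 (-2.90) lower on both scales and HD-GYP gene Bd1822 (1.47) higher. Counts adjusted over the list alone were equal in the other lists of these 3 paragraphs, and no list reached adjusted p under 0.05 with an estimated correlation.

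Ranked by reads per gene, without scaling by gene length, the highest genes in HEPES were Bd2212 (hypothetical, 87400 ± 901 CPM), Bd2723 (bacteriocin, 73600 ± 2720) and Bd2209 (hemolysin-type calcium-binding protein, 48800 ± 444). A ranking by transcript number may differ, since longer genes collect more reads. In NB they fell to 8220 ± 184, 5800 ± 411 and 4610 ± 258 CPM, and they were lower as shares of reads too. By the same ranking of reads per gene, Bd2913 (9120 ± 1180 CPM), Bd2212 and Bd1483 (7260 ± 1660) were highest in NB, where hypothetical genes Bd2913 and Bd1483 rose by 0.63 ± 0.13 and 0.67 ± 0.15.

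The authors' deposited table compares mean RPKM, a share-of-reads scale. It gives a ratio for 3446 genes, of which 2880 lie above 1 and 565 below, with a median of 4.65. With the authors' p under 0.05, the deposited ratio is at least 2 for 2128 genes and at most 0.5 for 204.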

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

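HEPES thinning, curated lists (also with an estimated correlation) and upper-quartile factors for named genes were chosen after seeing the data. The count of 2566 changed genes stayed between 1756 (a test against a 2-fold change) and 2988 (limma, no filter on low values), and between 2473 and 2569 when single samples were left out. Without rRNA and tRNA features nothing moved, because they were all at 0. With HEPES counts thinned to the NB depth 2372 of 2911 genes tested changed, and DESeq2 called 2404. Library totals and the limma settings moved the split of directions. For higher genes (1360), library totals gave 2421, limma on log2(RPKM + 1) 2412, with 0.1 in place of 1 2406, and with no filter 2596. For lower genes (1206) these settings gave 400, 395, 392 and 392. At 2-fold or more, they gave 2175, 2153, 2177 and 2315 higher (1101 with TMM) and 215, 209, 215 and 212 lower (933 with TMM). For library totals, which change the scale alone, the near-constant offset of 2.16 in log2 set by the TMM factors accounts for this. The limma settings change the test as well, and 1 of them the filter, and their causes were not tested apart. RLE factors, upper-quartile factors and DESeq2, which also differs in its test, kept 2497, 2441 and 2394 of the 2566 calls in the same direction. They gave 0 calls of the opposite direction and moved the median log2 fold change of all genes from 0.22 to 0.11, 0.47 and 0.11. Like TMM, these settings centre the bulk of genes, so their shared directions cannot decide between the TMM scale and library totals. Library totals kept 1760 and turned 586.

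With replicate number as a block, edgeR called 2542 genes and camera 12 lists, the predation-cycle loci being the added one (adjusted p = 0.0488). Deviations from the mean of each medium gave no sign of pairing by number. Their correlations across genes in HEPES and NB samples of the same number were -0.04, 0.07 and -0.01. With the block 2033 genes changed at least 2-fold, against 2034 without. These values cannot tell whether samples of the same number came from the same culture.

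Of 30 lists, 11 passed camera, among them the flagellum and the flagellin filament loci, which all lie on the flagellum list. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05), nor did any curated list (0, and 1 at an unadjusted p under 0.05), fry called 26 in 1 direction and 30 in either direction, and other settings gave between 10 and 13. On library totals the direction of chemotaxis (adjusted p = 0.954; 0.141 to 0.954 over the camera alternatives), gliding motility (0.79; 0.79 to 0.984) and proteases (0.714; 0.714 to 0.929) reversed. That of lipopolysaccharide (0.249) and peptidoglycan (0.00728) reversed with fry, and that of peptidoglycan (0.927, and 0.93 with an estimated correlation; 0.697 to 0.979) in curated lists; the cause was not tested. With single samples left out, gliding motility ran from 0.841 to 0.984, reversing without NB replicate 1.

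Of 143 named genes, 125 kept direction and side of the threshold on library totals and 142 with DESeq2. Those that reversed on library totals, and on log2(RPKM + 1) with limma, were Bd3401 (0.41 and 0.41), Bd3178 (1.24 and 1.23), Bd3256 (0.03 and 0.03), Bd1872 (0.05 and 0.04), Bd2996 (1.48 and 1.45), Bd0367 (1.39 and 1.38), Bd0468 (1.84 and 1.77), Bd0742 (1.76 and 1.72), Bd1075 (0.82 and 0.81), Bd1290 (0.77 and 0.78), Bd3279 (1.82 and 1.75), Bd0604 (0.33 and 0.33), Bd0410 (0.99 and 0.98) and Bd0606 (0.70 and 0.69). At this depth 545 genes had too few counts to be tested, and 22 tested genes had 1 to 3 HEPES counts in total.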

Other observations

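The comparison of the 100 most abundant HEPES genes left out of the totals, the test of a mixed population and 1 of the tests on neighbouring genes were chosen only after the result was seen, as were the gene runs, functional categories and shares of hypothetical genes described here. Among genes that changed at least 4-fold, 34 runs of at least 5 consecutive genes lay on 1 strand and changed in the same direction. The longest held 32 consecutive genes from Bd2949 to Bd2984 (bases 2859721 to 2885476), mostly ribosomal proteins with elongation factor G and RNA polymerase subunits, with a median log2 fold change of 4.18. Runs of 10 genes with ATP synthase subunits (Bd3896 to Bd3906, median 4.17) and 8 with cytochrome c and molybdopterin oxidoreductase genes (Bd1604 to Bd1612, 4.15) also rose. Among falls, 12 genes of a flagellar region (Bd3318 to Bd3329) had a median of -2.81, with 1 member higher as a share of reads. A run of 11 genes from the host-interaction locus through Flp pilus genes (Bd0108 to Bd0119) had a median of -3.53 (-1.36 as a share of reads). The gliding and TolQ cluster (Bd0412 to Bd0420, 9 genes, -4.26, and -2.10 as a share of reads) also fell. In 1000 shuffled gene orders the longest run held 8 genes, against 32 here.

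By functional category of the deposited annotation, translation (J) had 127 of 155 genes higher, energy production (C) 73 of 97 and motility (N) 37 of 42 lower, of which the median share of reads also fell (-0.58). Adjusted camera p with an estimated correlation was 0.379, 0.379 and 0.304. Genes called hypothetical made up 42.1% of those that fell and 23.5% of those that rose (odds ratio 2.37, 95% interval 1.99 to 2.82; Fisher's exact p = 1.23e-23, across genes, which are not independent replicates). Among the genes lower on both scales the share was 46.6%. The lists of the 100 most abundant genes of each medium had 62 genes in common.

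With 3 against 3 samples only 10 splits exist, too few for a share under 0.05. The real split gave 2566 changed genes, 2034 at least 2-fold and 11 lists. The highest of the others was 0 and 0 genes by edgeR (3 at an unadjusted p under 0.05). For lists the other splits gave from 7 to 12, so that the number of lists called with the preset correlation does not set the real split apart. As many lists as in the real split came from 2 of the 10 splits, and as many genes, by either count, from 1 of 10. Each other split sets 2 samples of 1 medium and 1 of the other against the reverse. It keeps part of the difference between media and adds that difference to the spread within groups. These splits therefore do not show what samples without a difference between media would give.

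Most genes held a higher share of reads in NB (median log2 change 2.39), while 91 of the 100 genes most abundant in HEPES held a lower one. Coding length is argued against, since the median was at least 2.22 in short, middle and long genes. With HEPES counts thinned to the NB depth the median was 2.38. Random thinning keeps the expected share of reads of each gene, so this value could hardly move and cannot decide on depth. Leaving those 100 genes out of the totals brought the median to 1.26, so they account for part but not all of it. A mixture of unchanged attack-phase RNA with RNA lacking these transcripts would lower all 100 alike, but their changes spread by an SD of 1.03, with a median SE of 0.08. A broad response to NB, a mixture of responding and unchanged cells, and a change in RNA per cell, which these data do not measure, stay open.

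A hypothesis that NB starts chromosome replication, which may raise gene copy number near the origin, was tested by position. The rank correlation of log2 fold change with distance from dnaA (Bd0001) was 0.00376 across 3041 genes (circular-shift p = 0.735), which gives no sign of such a gradient. No test of DNA content was possible from these data.

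Neighbouring genes on the same strand changed alike, with a median difference of 0.81 in log2 fold change, against 1.26 for opposite-strand neighbours and 2.15 for random pairs. The gap of 0.45 (permutation p = 1e-05, the smallest that 100000 resamples can give) is consistent with shared transcription units. The test of reads shared by overlapping genes that was planned first, on same-strand neighbours at least 50 bases apart, gave a gap of -0.1, as sharing predicts, but distance also parts transcription units. A test chosen after that value took neighbours that share no annotated base, lie 0 to 49 bases apart and are both at least 500 bases long. Their gap was 0.61. A 50 bp read can still reach both genes of such a pair, so this value cannot exclude shared reads. Sharing of reads therefore stays open, as does whether shared transcription units exist as single transcripts.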
